A study of Mus musculus with 8 samples.

How the data were processed

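RNA labelled as from the cervical spinal cord of male C57BL/6 mice was measured in 4 groups of 2 samples, on 8 arrays. Per the labels' protocols, RNA was extracted with a column kit, 300 ng of total RNA was turned into fragmented, biotin-labelled cDNA with the Affymetrix whole-transcript sense target assay, and the mice were 6 weeks old. MPTP was given at 20 mg/kg every 24 h for 4 weeks, and needling was done every 48 h, 2 h after MPTP, in 14 sessions, to depths of 3 mm at GB34, 1 mm at LR3 and 3 mm at the hips, per the labels' protocols. The submitters' processing notes name Affymetrix Expression Console and RMA, with no versions or chip library files given in the sources used here. RMA corrects background, makes the distribution of probe signals equal across arrays and summarises the probes of each probe set on a log scale. The authors deposited 1 log2 value per probe set and array, 35557 probe sets in all, where the base of the log was read from the range of the values. The median over all probe sets was 5.80 and 5.77 on the control arrays, 5.61 and 5.64 on the MPTP arrays, 5.71 and 5.60 on the acupoint arrays, and 5.59 and 5.65 on the non-acupoint arrays, in the order of replicates 1 and 2. For probe sets without a gene symbol it was 4.75 on both control arrays and 4.25 to 4.39 on the others, and for the genes tested 7.014 and 6.997 on the control arrays and 7.05 to 7.11 on the others, so the 2 kinds of probe set differed between control and treated arrays in opposite directions. The standard deviation of the values was 2.35 on both control arrays and 2.43 to 2.50 on the others, so arrays differ in overall distribution after the authors' normalization. Scanner files and scan dates were not used here, so no batch could be tested. RMA values keep no measure of signal over background per probe set, and the signal of dim probe sets understates fold changes.

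Probe sets were named through the platform annotation, which gave 1 gene symbol for 21789 probe sets, several for 1621 and none for 12147. Of the 21789, the Entrez identifiers of 21698 were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed renaming. No genome was used, so no coordinates are given. Probe sets with 1 symbol were kept where the mean over the 8 arrays was above the 30th percentile of all probe sets, 4.30 on the log2 scale, which left 17581. For the 865 genes with more than 1 such probe set the one with the highest mean was taken, and 16026 genes were tested. No gene is named from a probe set with several symbols, and probe sets without a symbol entered only an alternative over every probe set.

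Groups were taken from the labels. A linear model with 1 mean per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 4 residual degrees of freedom and 5.34 prior degrees of freedom, and p-values are two-sided. The 7 contrasts were MPTP minus control, each needled group minus MPTP, acupoint minus non-acupoint needling, each needled group minus control, and the mean of the 3 MPTP groups minus control, with an F-test over the 4 groups. Benjamini-Hochberg adjustment was made within each contrast, and an adjusted p under 0.05 was called. A set of 42 gene lists was fixed, of which 40 had at least 5 genes tested. Lists were tested with camera at a preset correlation of 0.01, and p-values were adjusted over 40 lists and 7 contrasts together. The same lists were tested with camera with a correlation estimated from the residuals, and with fry, which asks whether the genes of a list move, on balance, in 1 direction. No list kept its call with an estimated correlation. A count described as adjusted over the list alone applies the adjustment to the limma p-values of that list's genes.

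The share of variance between groups was compared with all 105 ways of splitting the 8 arrays into 4 pairs (15 ways for the 6 treated arrays), and covariances between contrasts with all 2520 assignments of the arrays to groups. Expected covariances without effects came from 100 simulated data sets. With 2 arrays against 2 there are 3 splits and the smallest exact permutation p for 1 gene is 0.333, so single genes rest on the moderated test. The design, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. For each of the 4 main comparisons the rule took, among genes without overlap between the arrays of the 2 groups, the 12 with the largest positive and the 12 with the largest negative log2 difference among those past the adjusted threshold, filled up by genes at an unadjusted p under 0.01, which are said not to pass. For the 3 other contrasts it took 4 in each direction. For each list described it took the 2 to 4 members with the smallest p and any member that passed adjusted over the list alone. Predicted genes without a common name, olfactory and vomeronasal receptors and small RNAs were counted but not named. Genes named in 1 comparison could be followed in the others.

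The alternatives were quantile normalization of the deposited values again, cyclic loess, centring each array on its median, no filter, a filter at the 50th percentile, eBayes without a trend, robust eBayes, no moderation, only the 2 groups compared, array weights, the average of a gene's probe sets, every probe set, the replicate number as a block, and each array left out in turn. Covariates for muscle and for nerve and meninges markers, leaving out acupoint replicate 1 and non-acupoint replicate 1 together, leaving out single arrays from the variance share, comparing acupoint replicate 2 with MPTP replicate 1 alone, and no-change covariances for each array left out and from the MPTP arrays alone were added after seeing the data. The tests were checked on simulated data for 16026 genes, 200 of which were changed. For MPTP minus control 38.8% of genes changed 1.41-fold, 97.0% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 9 false among 166 calls. For acupoint needling minus MPTP the shares were 31.3%, 98.5% and 100% (9 false of 162), for non-acupoint needling minus MPTP 37.3%, 95.5% and 100% (13 of 168), and for acupoint minus non-acupoint needling 46.3%, 95.5% and 100% (8 of 169). Simulated genes varied independently and with the same spread in every group, so these shares can overstate recovery on the real arrays. In the data Sgk3, 2.69-fold lower in acupoint minus non-acupoint needling, was not called (limma adjusted p = 0.411). A simulated list shifted by 0.3 was called, and 0 of the other 39 were. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.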

Results

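Gene expression was measured with 8 whole-transcript arrays in tissue labelled as cervical spinal cord of male C57BL/6 mice. MPTP, a neurotoxin that destroys dopaminergic neurons and is used to model parkinsonism in mice, was injected at 20 mg/kg for 4 weeks, and control mice received saline. Of the MPTP groups, the first was left without needling, the next was needled by hand at the leg and foot acupoints GB34 and LR3 in 14 sessions, and the last was needled at both hips, away from these acupoints (the non-acupoint group, also called hip needling). Each of the 4 groups had 2 arrays, called replicate 1 and replicate 2 below, and every comparison set 2 arrays against 2 unless stated otherwise. The labels number a mouse for each array and describe extraction of 2 samples per group, while the treatment protocol gives more mice than that for the control and MPTP groups. Whether an array holds the RNA of a single mouse or of a pool is not given in the sources used here, so the p-values and SEs measure only the spread between these samples, which may be technical. The number of arrays limits the precision, and log2 differences are given with the standard error (SE) of the model fitted to all 8 arrays.

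Across 16026 genes, the correlation between the 2 control arrays was 0.988, between control and treated arrays 0.975 to 0.988, and among the 6 treated arrays 0.985 to 0.996. Control replicate 1 correlated with acupoint replicate 1 as closely as with control replicate 2 (0.988 each), and the 2 acupoint arrays correlated at 0.985. These are correlations across genes, which are not independent replicates. The 4 groups held 60.1% of the variance (12 of the 105 ways of pairing the arrays gave a share as large, exact permutation p = 0.114). Among fits with 1 array left out, added after seeing the data, the largest share was 73.8%, without acupoint replicate 2. That fit leaves acupoint replicate 1 as a group of its own with no spread within it, so it does not show that the groups separate. Within the 6 treated arrays the 3 groups held 33.5%, below the 38.5% of the median pairing (exact permutation p = 0.8). The limma F-test over the 4 groups called 1724 genes. Leaving out 1 array gave 640 genes without control replicate 1, 20 without control replicate 2, 409 and 477 without MPTP replicates 1 and 2, 3567 and 4030 without acupoint replicates 1 and 2, and 633 and 692 without non-acupoint replicates 1 and 2.

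The comparison of MPTP with saline asked how the samples of these 2 groups differed. Alas2, the first enzyme of haem synthesis in erythroid cells, was 5.48-fold higher after MPTP (log2 2.45, SE 0.38, adjusted p = 0.00543). The other 3 erythroid genes measured, Slc4a1, Bpgm and Fech, were at 0.13, 0.15 and 0.095 and did not pass. Only 4 of the 14 genes on the erythroid and blood list were measured, too few for a list test. Whether the samples differed in blood was therefore not tested. The nucleosome-binding protein gene Hmgn5 rose 3.38-fold (log2 1.76, SE 0.33, adjusted p = 0.00905), and the platelet chemokine gene Ppbp rose 3.22-fold (log2 1.69, SE 0.49, adjusted p = 0.044). Etnppl, an astrocyte-enriched phospholyase gene, rose by 1.24 (SE 0.16), Car5b, a mitochondrial carbonic anhydrase gene, by 1.2 (SE 0.17), and Htatsf1, a transcription and splicing factor gene, by 1.15 (SE 0.13). Angpt1, a ligand of the Tie2 receptor, rose by 1.15 (SE 0.23), and Dmp1, Fads2b, Sp140, Zfp605 and Ipp rose by 1.13 to 1.26. The imprinted non-coding RNA Rian fell 4.26-fold (log2 -2.09, SE 0.12) and had the smallest adjusted p of all genes, 0.000227. The other 11 genes with the largest negative differences encode contractile or energy proteins of skeletal muscle. They ran from Atp2a1, the calcium pump of fast fibres (log2 -3.51, SE 0.66, adjusted p = 0.00927), to the muscle phosphoglycerate mutase Pgam2 (log2 -1.84, SE 0.35, and -1.21 without control replicate 2). For these genes an effect of MPTP was not told apart from muscle tissue in the control samples, which is taken up below.

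In all, 2696 of 16026 genes passed an adjusted p of 0.05 in limma, 2199 higher and 497 lower, of which 27 and 67 changed at least 2-fold. Arrays of the 2 groups did not overlap for 10261 of 16026 genes, above the chance share of 33.3%. Both the scaling of the arrays and single arrays moved these counts. After cyclic loess the split was 1338 higher and 752 lower, and with each array centred on its median it was 4028 and 218, with the median gene shifted from 0.061 to 0.22. The count was 681 without control replicate 2, 69 without MPTP replicate 1, 194 without MPTP replicate 2, and 4225 and 4202 without acupoint replicates 1 and 2, which enter through the shared estimate of the spread. The median signal of the tested genes was 7.014 and 6.997 on the control arrays and 7.05 to 7.11 on the 6 treated arrays, while that of probe sets without a gene symbol was 4.75 on both control arrays and 4.25 to 4.39 on the treated arrays. Of the 24 genes named by size, only Etnppl, Htatsf1 and Rian passed without MPTP replicate 1. Car5b, Tnnt3 and Ttn joined them without MPTP replicate 2, and Alas2, Dmp1, Neb, Pgam2 and these 6 passed without control replicate 2, while Ppbp was also lost without control replicate 1. The log2 differences of these 24 genes were 0.918 to 1.08 times those of all arrays without MPTP replicate 1 and 0.923 to 1.08 times without MPTP replicate 2, so these calls ended where 1 array stood for a group, with differences of about the same size. Without control replicate 2 they were 0.654 to 1.16 times (median 0.806).

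**Figure D1:**
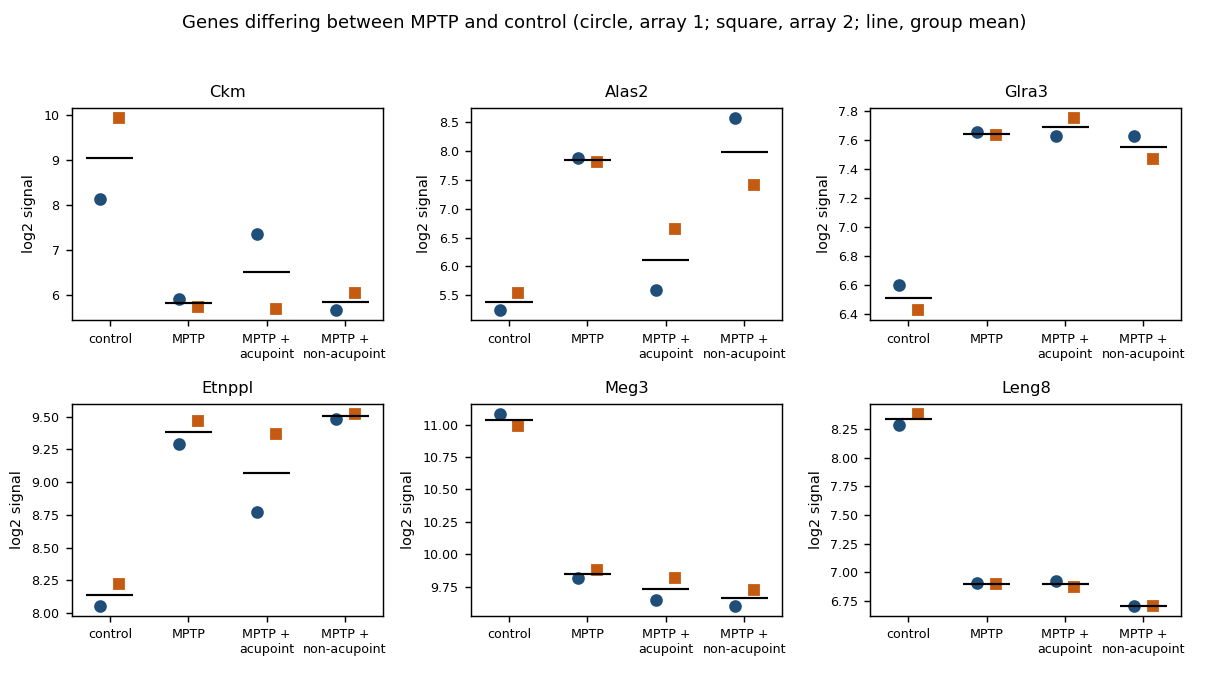
Log2 signal of 6 genes on each of the 8 arrays (y axis) by group (x axis), with a circle for replicate 1, a square for replicate 2 and a line for the group mean. Ckm, Meg3 and Leng8 were highest on the control arrays, Alas2, Glra3 and Etnppl were lowest there, and Ckm on acupoint replicate 1 lay at 7.36, between the control arrays and the other treated arrays.

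Skeletal muscle transcripts had a mean log2 difference of -2.39 over 15 genes. All 15 fell adjusted over the list alone and 11 over all genes (camera adjusted p = 1.4e-12, adjusted p = 0.818 with an estimated correlation). Log2 differences were -3.32 (SE 0.72) for the myosin heavy chain Myh4, -3.31 (SE 0.48) for the troponin T gene Tnnt3, -3.21 (SE 0.59) for the creatine kinase Ckm, -3.14 (SE 0.60) for the myosin light chain Myl1, -2.87 (SE 0.61) for the actin Acta1 and -2.82 (SE 0.38) for titin, Ttn. Actn3 (-2.08), Tnnc2 (-1.99), Mylpf and Tnni2 fell as well, as did nebulin, Neb (-2.33), which is not on the list. Pvalb, which spinal neurons also express, Myh1, Myh2 and Mb passed over the list alone only. The mean of these markers was 7.48 and 8.94 on control replicates 1 and 2 and 6.99 on acupoint replicate 1, against 5.56 to 5.94 on the other 5 arrays. It thus differed within the control and acupoint groups too, and muscle tissue in some samples was not told apart from an effect of MPTP. Among non-coding and splicing-related transcripts, chosen after their values were seen, Meg3 fell by 1.19 (SE 0.08), Malat1 fell by 1.19 (SE 0.12) and Leng8 fell by 1.44 (SE 0.09), and Snhg11 and Wsb1 were at -1.43 (SE 0.14) and -1.17 (SE 0.10), all past the threshold.

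Of 17 GABA and glycine genes, which serve inhibitory transmission, 11 rose after MPTP over all genes and 12 adjusted over the list alone, while 3 were negative without passing. The list mean was 0.39 (camera adjusted p = 0.000231, adjusted p = 0.808 with an estimated correlation). The glycine receptor subunit Glra3 rose by 1.13 (SE 0.11), the GABA-A receptor subunits Gabrb1, Gabra3 and Gabrb2 by 0.66, 0.66 and 0.51, and the GABA-synthesising enzymes Gad1 and Gad2 by 0.41 and 0.48. Glrb, Gabra2, Slc6a9, Gphn and Glra2 rose as well, and Glra1 (0.21) passed over the list alone only. Motor neuron genes had a mean of 0.37 (camera adjusted p = 0.00148, adjusted p = 0.818 with an estimated correlation), and 9 of 16 rose by both adjustments. Among them were Slc5a7 (0.80) and Chat (0.82), which take up choline and make acetylcholine, Chodl (0.82), Mmp9, Prph and Gfra1, and the neurofilament genes Nefh, Nefl and Nefm. Of 15 pan-neuronal genes 8 rose by both adjustments, led by Eno2 (0.62), Celf4 (0.58) and the synaptic Snap25 (0.44), followed by Syp, Syt1, Stmn2, Elavl2 and Elavl3 (list mean 0.26, camera adjusted p = 0.00545, adjusted p = 0.818 with an estimated correlation). Dorsal horn peptides and receptors had 7 of 21 members higher by both adjustments, namely the neuropeptide Y receptor Npy1r (0.89), Calcb (0.75), Nts (0.67), Tacr3, Trh, Grpr and Tacr1 (list mean 0.33, camera adjusted p = 0.0199, adjusted p = 0.908 with an estimated correlation).

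Astrocyte markers, microglial markers and heat shock genes had positive list means. The astrocyte markers had a mean of 0.40 (camera adjusted p = 4.32e-05, adjusted p = 0.808 with an estimated correlation), and 11 of 15 rose by both adjustments. These included the glutamate transporters Slc1a3 (0.80) and Slc1a2 (0.48), the folate enzyme Aldh1l1 (0.74), angiotensinogen Agt (0.69), the water channel Aqp4, the gap junction genes Gja1 and Gjb6, and Fgfr3, Ntsr2, Glul and Gfap. Of 23 microglia and macrophage markers 8 rose, and 9 adjusted over the list alone, among them the protease Ctss (0.74), the integrin Itgam (0.61), the complement genes C1qa and C1qb (0.46 and 0.47), Cx3cr1, Gpr34, Aif1, Siglech and, over the list alone, Fcrls. The microglial list mean was 0.25 (camera adjusted p = 0.0373, adjusted p = 0.854 with an estimated correlation), and its adjusted p was 0.175 without control replicate 2 (mean 0.16), 0.0545 without MPTP replicate 2, and 0.0603 and 0.0564 without acupoint replicates 1 and 2. Of 14 heat shock genes 7 rose, and 9 adjusted over the list alone, with the small chaperone Hspb1 at 0.89, the endoplasmic reticulum chaperone Hspa5 at 0.59 and Hsp90aa1 at 0.38, followed by Dnajb1, Hsph1, Dnaja1, Chordc1, Hspd1 and Hspa8 (list mean 0.27, camera adjusted p = 0.0102, adjusted p = 0.808 with an estimated correlation). After a further quantile normalization and after cyclic loess, the adjusted p was 0.153 and 0.227 for the heat shock genes and 0.144 and 0.217 for the pan-neuronal genes. After cyclic loess the list mean was 0.11 for pan-neuronal genes, 0.13 for heat shock genes, 0.25 for astrocyte markers and 0.24 for GABA and glycine genes. With arrays centred on their medians it was 0.41 for pan-neuronal genes, 0.43 for heat shock genes and 0.41 for microglial markers. Camera did not match genes on expression. Random lists matched in expression to the nuclear-retained RNAs described below had a median of 0.155 in MPTP minus control, against 0.061 over all genes. No such baseline was computed for the neuronal, glial and heat shock lists, so part of their means may be shared by genes of like signal. The muscle markers were lower on every treated array than on either control array, and so moved with each of these groups.

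Cytosolic ribosomal protein genes had a mean of -0.15 (camera adjusted p = 2.93e-05, adjusted p = 0.854 with an estimated correlation), and this mean turned to 0.0094 when the arrays were centred on their medians, which is -0.21 relative to the median gene. After cyclic loess it was -0.28, and it was -0.23 and -0.068 without control replicates 1 and 2, still called. Of 33 genes 6 fell over all genes (Rps12, Rps14, Rps28, Rpl7, Rpl12 and Rpl24, at -0.27 to -0.61) and 7 adjusted over the list alone, with Rpl27 added. Several lists tied to the disease model had single members past the threshold without a call for the list. Over all genes 2199 of 16026 passed higher and 497 lower, so lists of this size hold some such members by that share alone. Among 15 catecholamine genes the dopamine-degrading enzymes Maoa and Maob rose by 0.58 and 0.70 and the decarboxylase Ddc by 0.71, by both adjustments (list mean 0.18, camera adjusted p = 0.53). The rate-limiting enzyme of dopamine synthesis, Th, was at 0.45 (SE 0.23, adjusted p = 0.207). Of 13 familial parkinsonism genes Vps35 rose by 0.34 and Vps13c fell by 0.33 (camera adjusted p = 0.996). The opioid genes Pdyn, Oprk1 and Oprl1 rose by 0.82, 0.67 and 0.50 over all genes and Pnoc (0.39) passed over the list alone, making 4 of 8 (camera adjusted p = 0.0575). Among 18 glucocorticoid-responsive genes Fkbp5 (0.84), Sgk1 (0.50), Plin4 (0.58), Mt2 (0.43) and Klf9 (0.28) rose and Hif3a (-0.56) fell by both adjustments (camera adjusted p = 0.39). Of 16 clock genes Cry1, Cry2, Clock and Bhlhe41 rose by 0.65, 0.32, 0.35 and 0.37, and Nr1d1 (-0.67) and Per3 (-0.58) fell, by both adjustments (camera adjusted p = 0.963).

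**Figure D2:**
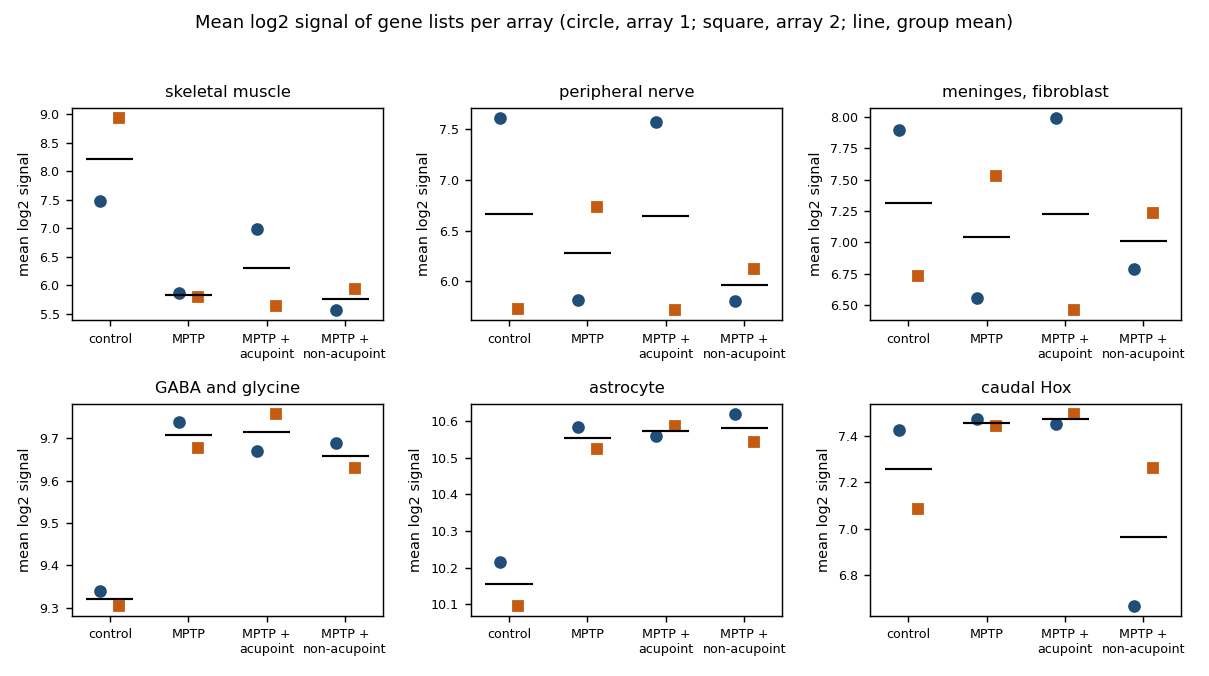
Mean log2 signal of 6 gene lists on each array (y axis) by group (x axis), with a circle for replicate 1, a square for replicate 2 and a line for the group mean. Muscle markers were highest on the 2 control arrays and acupoint replicate 1 (6.99), peripheral nerve and meninges markers were high on control replicate 1 and acupoint replicate 1, GABA and glycine genes and astrocyte markers were lowest on the control arrays, and caudal Hox genes were lowest on non-acupoint replicate 1 (6.67).

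The comparison of acupoint needling with MPTP alone asked which transcripts acupuncture moved in treated mice. No gene passed the adjusted threshold, and the genes named here had an unadjusted p under 0.01, an adjusted p of 1 and no overlap between the arrays. Sprr1a, which is induced in injured sensory neurons, was 1.89-fold higher after acupoint needling (log2 0.92, SE 0.18). The immediate early gene Jun was at 0.30 (SE 0.09), the integrin subunit Itga4 at 0.47 (SE 0.12), Gal3st2c at 0.53 (SE 0.15), Tmem150a at 0.49 (SE 0.13) and the splicing scaffold gene Srrm2 at 0.22 (SE 0.07). Alas2 was at -1.73 (SE 0.38), with 5.59 and 6.64 on the acupoint arrays against 7.87 and 7.81 on the MPTP arrays. The kinase gene Sgk1, which had risen after MPTP, was at -0.58 (SE 0.10), and its level of 8.14 ± 0.11 (SD, n = 2) was close to the control level of 8.22 ± 0.10 (SD, n = 2). Both Sgk1 differences contain the MPTP arrays, so high values there by chance would give a rise and then a fall. Hoxc5, the interferon-induced conjugating enzyme Ube2l6, Ctla2a and the repressor Bcl6 were at -0.69, -0.60, -0.46 and -0.40.

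The limma count of 0 genes went with 201 genes at an unadjusted p under 0.05. The fit without moderation also gave 0 genes, with 321 at an unadjusted p under 0.05, array weights gave 0, and leaving out acupoint replicate 2 gave 3. Arrays did not overlap for 3888 of 16026 genes, below the chance share of 33.3%. In camera, 7 lists passed, none of them with a member past the threshold over all genes or adjusted over the list alone. Complex I genes had a mean of -0.11 (adjusted p = 1.12e-05, adjusted p = 0.908 with an estimated correlation). Cholesterol synthesis genes had a mean of 0.10 (adjusted p = 1.12e-05, adjusted p = 0.818 with an estimated correlation), ribosomal protein genes of -0.081 (adjusted p = 0.000573, adjusted p = 0.908 with an estimated correlation) and the genes of ATP synthase and complexes II to IV of -0.057 (adjusted p = 0.00425, adjusted p = 0.923 with an estimated correlation). Sgk1 passed adjusted over the list of glucocorticoid-responsive genes alone, a list that was not called. Muscle markers had a mean of 0.48 (adjusted p = 0.00395, adjusted p = 0.914 with an estimated correlation), antigen presentation genes of 0.18 (adjusted p = 0.0114, adjusted p = 0.912 with an estimated correlation) and neurotrophic factors and receptors of 0.073 (adjusted p = 0.0481, adjusted p = 0.832 with an estimated correlation). After a further quantile normalization and after cyclic loess, the mean was -0.027 and -0.022 for ATP synthase and complexes II to IV, no longer called (adjusted p = 0.169 and 0.227), and -0.0535 and -0.051 for ribosomal proteins, still called. The neurotrophic list was lost with both (adjusted p = 0.0613 and 0.069), without the filter on dim probe sets (0.0798) and with the replicate block (0.0575), and its mean was 0.048 with arrays centred on their medians.

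Acupoint replicate 1 carried most of these list differences. It held more transcripts of peripheral nerve (list mean 7.57, against 5.71 on acupoint replicate 2), meninges (7.99 against 6.46) and muscle (6.99 against 5.63). The MPTP arrays were uneven too, with nerve markers at 5.82 and 6.73 and meninges markers at 6.56 and 7.53 on replicates 1 and 2. Without it the mean was -0.20 for muscle, 0.0080 for complex I, -0.12 for antigen presentation, -0.052 for neurotrophic factors, 0.0022 for ATP synthase and complexes II to IV, and -0.022 for ribosomal proteins, and of the 7 lists only cholesterol synthesis still passed. Cholesterol synthesis was lost without acupoint replicate 2 (mean 0.064, adjusted p = 0.0746), where the other 6 stayed called at means of 1.16 for muscle, 0.49 for antigen presentation, 0.20 for neurotrophic factors, -0.23 for complex I, -0.14 for ribosomal proteins and -0.12 for ATP synthase and complexes II to IV. Without MPTP replicate 1 the adjusted p was 0.491 for antigen presentation (mean 0.010), 0.265 for neurotrophic factors (mean 0.025) and 0.0574 for ATP synthase and complexes II to IV. Without MPTP replicate 2 the means of antigen presentation, neurotrophic factors and cholesterol synthesis were 0.36, 0.12 and 0.0605, all still called. The neurotrophic list was also lost without either control array (0.0563 and 0.0589) and without either non-acupoint array (0.0527 and 0.0503).

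The comparison of hip needling with MPTP alone asked what needling away from the acupoints changed. No gene passed here either, and the genes named had an unadjusted p under 0.01, an adjusted p of 1 and no overlap between the arrays. Sprr1a was 2.19-fold higher after hip needling (log2 1.13, SE 0.18), and the stress-induced transcription factor Atf3 was at 0.62 (SE 0.17). The kinase gene Sgk3 was at 0.97 (SE 0.19), the transcription factor Zbtb16 at 0.94 (SE 0.23) and the lipid droplet protein Cidea at 1.16 (SE 0.35). Tecrl, the purine oxidase Xdh, Rhoj, Trim59, Zfp459, the triglyceride-synthesising Dgat2 and the cell cycle inhibitor Cdkn2c were at 0.52 to 0.91. The positional genes Hoxd11 and Hoxd9 were at -1.30 (SE 0.40) and -0.57 (SE 0.15), and Sgk1 was at -0.54 (SE 0.10). Dnah7b was at -0.61, with its other probe set at 0.07, and Mmp14, Banp, Ints2, the neuropeptide gene Trh, Zfp36l1, the glucocorticoid-activating Hsd11b1, Trib2 and the thyroid hormone transporter Slco1c1 were at -0.49 to -0.34.

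The limma count of 0 genes went with 273 genes at an unadjusted p under 0.05. The fit without moderation gave 0, with 384 at an unadjusted p under 0.05, array weights gave 1, Sgk3, and a fit to these 2 groups alone gave 2, Sgk3 and Zbtb16. Leaving out non-acupoint replicate 1 gave 13 genes, all higher after hip needling and including Cidea (log2 1.86), and leaving out non-acupoint replicate 2 gave 2, both lower. The fit with 13 genes rests on non-acupoint replicate 2, where 11 adipose markers, on a list written after the first results were seen, were higher than on the acupoint arrays by a median of 1.5 (Fabp4 at 9.05, against 4.25 to 4.99 on the other 7 arrays). Leaving out acupoint replicate 1 or acupoint replicate 2 gave Sgk3 and Zbtb16, at adjusted p of 0.0227 and 0.0151, or 0.0255 and 0.019. Arrays did not overlap for 5817 of 16026 genes, a little above the chance share of 33.3%. Microglial markers had a mean of 0.12 (camera adjusted p = 7.79e-06, adjusted p = 0.808 with an estimated correlation) and complement genes of 0.15 (adjusted p = 0.000106, adjusted p = 0.808 with an estimated correlation). Each list had 0 members past the threshold over all genes and 3 adjusted over the list alone: C1qa (0.39), C1qc (0.34) and the protease Ctss (0.31) among the first, and C1qa, C1qc and C4b (0.37) among the second. Glucocorticoid-responsive genes had a mean of 0.20 (adjusted p = 0.000573, adjusted p = 0.818 with an estimated correlation), with Zbtb16, Fkbp5 (0.51) and, in the other direction, Sgk1 past the threshold over the list alone. Without non-acupoint replicate 2 this mean was 0.076 (adjusted p = 0.513), and without non-acupoint replicate 1 it was 0.33. The complement mean was 0.081 without MPTP replicate 1 and 0.096 without the filter on dim probe sets, still called.

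Caudal Hox genes had a mean of -0.49 (adjusted p = 0.00143, adjusted p = 0.808 with an estimated correlation), with no member past the threshold by either adjustment. Of the 15 members 9 were negative and 6 positive (median -0.37). The list mean was 6.67 on non-acupoint replicate 1 and 7.26 on replicate 2, against 7.47 and 7.44 on the MPTP arrays and 7.43 and 7.08 on the control arrays, so control replicate 2 lay below non-acupoint replicate 2. Members went both ways on non-acupoint replicate 1, with Hoxd10 at 4.58 there and 7.64 to 9.07 elsewhere, and Hoxc8, chosen after its values were seen, at 10.19 there and 8.51 to 9.97 elsewhere. The mean was -0.20 without non-acupoint replicate 1 (adjusted p = 0.0194) and -0.79 without non-acupoint replicate 2. Rostral Hox genes had list means of 6.38 to 6.60 over the 8 arrays, below the caudal ones on each array. Signals of different probe sets are not directly comparable. The labels give cervical cord for every sample, a level that these values neither test nor bear out. Caudal Hox genes mark position along the cord, and whether all samples were dissected at the same level is not given in the sources used here. With non-acupoint replicate 1 and acupoint replicate 1 both left out, a setting added after seeing the data, the mean was -0.20 (adjusted p = 0.0569). The other lists called had means of -0.099 to 0.091 and no member past the threshold by either adjustment. They were cholesterol synthesis (adjusted p = 0.00148, adjusted p = 0.908 with an estimated correlation), oligodendrocyte markers (0.00395 and 0.818), dorsal horn peptides (0.00416 and 0.854), antioxidant genes (0.0057 and 0.854), interferon response (0.00744 and 0.908), reactive astrocyte genes (0.0123 and 0.912) and serotonin genes (0.0481 and 0.808, in the same order). Antioxidant genes passed whichever array was left out. Cholesterol synthesis and oligodendrocyte markers were lost without MPTP replicate 2 (means 0.034 and 0.031, adjusted p 0.16 and 0.153) and without non-acupoint replicate 1 (means 0.014 and 0.027, adjusted p 0.475 and 0.193), and had means of 0.12 and 0.099 without MPTP replicate 1 and of 0.14 and 0.10 without non-acupoint replicate 2. Interferon response and reactive astrocyte genes were lost without MPTP replicate 1 (means 0.063 and, turned, -0.0165, adjusted p 0.187 and 0.602) and without non-acupoint replicate 2 (means 0.057 and 0.034, adjusted p 0.353 and 0.25). The reactive astrocyte mean was 0.18 without MPTP replicate 2 and 0.13 without non-acupoint replicate 1. Dorsal horn peptides had a mean of -0.16 without non-acupoint replicate 1 and were lost without replicate 2 (mean -0.036, adjusted p 0.281). Serotonin genes were lost without any 1 of the 6 treated arrays (adjusted p 0.0503 to 0.269), after a further quantile normalization (0.0965), after cyclic loess (0.0791) and with the replicate block (0.056).

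The comparison of acupoint with hip needling asked whether the site of needling mattered. No gene passed, and the genes named had an unadjusted p under 0.01 and no overlap between the arrays. Sgk3 was 2.69-fold lower after acupoint needling (log2 -1.43, SE 0.19) and had the smallest adjusted p, 0.411, while the others had an adjusted p of 0.936. Alas2 was at -1.87 (SE 0.38), the glucocorticoid-induced chaperone Fkbp5 at -0.71 (SE 0.15), and the lipid and energy genes Cidea, Plin4, Ucp3 and Dio2, the last a thyroid hormone-activating enzyme, at -1.16, -0.62, -0.69 and -0.72. Tecrl, the chemokine Ccl3, Hoxc5, Pdlim1 and Ube2l6 were at -0.97 to -0.66. Hoxc10 and Hoxd9 were at 1.60 (SE 0.45) and 0.68 (SE 0.15), the deubiquitinase gene Usp17ld at 1.18 (SE 0.28) and the phosphatase gene Dusp4 at 0.56 (SE 0.16). Set, Ints2, Fam216b, Chst7, Snx31, Banp, Hpcal4 and the calcium channel subunit gene Cacng5 were at 0.43 to 0.59.

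**Figure D3:**
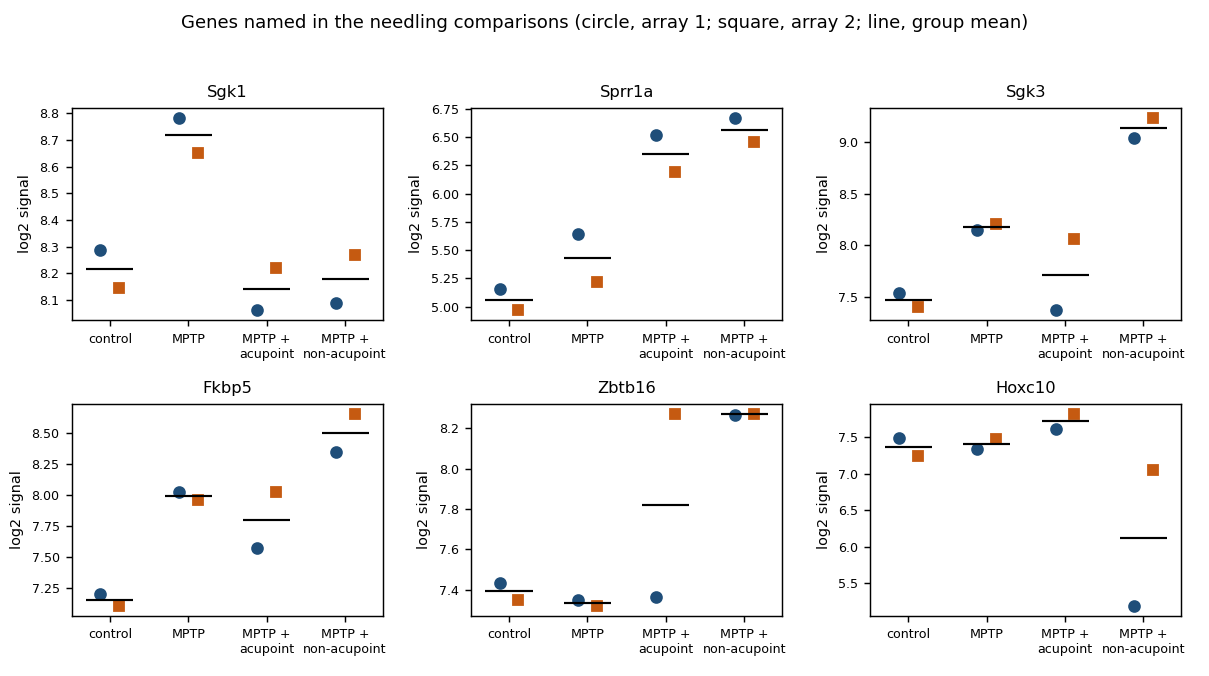
Log2 signal of 6 genes named in the needling comparisons on each array (y axis) by group (x axis), with a circle for replicate 1, a square for replicate 2 and a line for the group mean. Sgk1 in both needled groups lay near its control level, Sprr1a was higher on all 4 needled arrays than on the others, Sgk3 and Fkbp5 were highest after hip needling, Zbtb16 was at 8.27 on acupoint replicate 2 and both non-acupoint arrays, and Hoxc10 was lowest on non-acupoint replicate 1.

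The limma count of 0 genes went with 604 genes at an unadjusted p under 0.05, and the fit without moderation gave 0, with 583 at an unadjusted p under 0.05. Leaving out acupoint replicate 2 gave 622 genes, 82 higher and 540 lower after acupoint needling, among them Sgk3 (log2 -1.78), Alas2 (-2.40), Fkbp5 (-0.93), Ccl3, Dio2, Ucp3, Pdlim1, Usp17ld and Cacng5. That fit sets acupoint replicate 1, with its nerve, meninges and muscle transcripts, against the hip-needled arrays. Leaving out non-acupoint replicate 1, which leaves replicate 2 with its adipose transcripts, gave 12 genes, including Cidea (-1.86), and leaving out non-acupoint replicate 2 gave 3, including Hoxc10 (2.53). Arrays did not overlap for 4539 of 16026 genes, below the chance share of 33.3%.

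Complement genes and microglial markers, which share C1qa, C1qb and C1qc, had negative list means in acupoint minus hip needling. Antigen presentation, interferon response and cytokine genes were not called (adjusted p = 0.53, 0.226 and 0.972). Complement genes had a mean of -0.16 (camera adjusted p = 0.00138, adjusted p = 0.808 with an estimated correlation), with C1qa (-0.38), C4b (-0.36), C1qb and C1qc past the threshold over the list alone and none over all genes. Microglial markers had a mean of -0.11 (adjusted p = 0.00148, adjusted p = 0.818 with an estimated correlation), with Ctss (-0.34), C1qa and C1qb past it over the list alone. Glucocorticoid-responsive genes had a mean of -0.21 (adjusted p = 0.00175, adjusted p = 0.818 with an estimated correlation), with Fkbp5, Plin4 and the metallothioneins Mt2 (-0.40) and Mt1 (-0.24) past it over the list alone. Dorsal horn peptides had a mean of 0.13 (adjusted p = 0.000714, adjusted p = 0.818 with an estimated correlation), with the peptide genes Npy and Sst (0.40 each) past it over the list alone, and caudal Hox genes of 0.51 (adjusted p = 0.00395, adjusted p = 0.808 with an estimated correlation), with Hoxd9 and Hoxc10. Without acupoint replicate 2 the mean was -0.023 for complement (adjusted p = 0.338), -0.11 for microglia (0.0651), 0.49 for caudal Hox genes (0.261) and 0.0078 for dorsal horn peptides (0.581). Without acupoint replicate 1 it was -0.30 for complement and 0.25 for dorsal horn peptides, and without the filter on dim probe sets it was -0.085 for complement, all still called. Without non-acupoint replicate 2 it was -0.081 for glucocorticoid-responsive genes (adjusted p = 0.434), 0.068 for dorsal horn peptides (0.0505) and 0.81 for caudal Hox genes, the last still called. Without non-acupoint replicate 1 it was 0.21 for caudal Hox genes (adjusted p = 0.0135) and -0.33 for glucocorticoid-responsive genes, both still called.

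Another 8 lists were called with no member past the threshold by either adjustment, and for 7 of them the mean was much smaller or turned without acupoint replicate 1. Means were 0.68 for Schwann cell and peripheral nerve markers (camera adjusted p = 0.0183, adjusted p = 0.923 with an estimated correlation), 0.56 for muscle markers (0.00371 and 0.914) and -0.092 for complex I genes (0.00232 and 0.923). Antioxidant genes had a mean of -0.11 (adjusted p = 0.000658, adjusted p = 0.818 with an estimated correlation), neurotrophic factors of 0.12 (0.0057 and 0.818), immediate early genes of 0.12 (0.00781 and 0.818), serotonin genes of 0.11 (0.0246 and 0.808) and ribosomal protein genes of -0.068 (0.0057 and 0.921). Without acupoint replicate 1 none of these 8 lists passed, and the mean was -0.25 for nerve, -0.12 for muscle, 0.027 for complex I, -0.0071 for neurotrophic factors, -0.036 for antioxidant genes, 0.019 for immediate early genes and -0.0094 for ribosomal proteins. For serotonin genes only the call was lost (mean 0.10, adjusted p = 0.0511), as it was without acupoint replicate 2 (0.159). The other 7 stayed called without acupoint replicate 2, at means of 1.60 for nerve, 1.24 for muscle, -0.21 for complex I, -0.18 for antioxidant genes, 0.24 for neurotrophic factors, 0.21 for immediate early genes and -0.13 for ribosomal proteins. Without non-acupoint replicate 1 the adjusted p was 0.184 for nerve, 0.163 for muscle (mean 0.37), 0.154 for neurotrophic factors (mean 0.070), 0.114 for serotonin genes and 0.115 for ribosomal proteins (mean -0.042). After a further quantile normalization and after cyclic loess, the mean was -0.0265 and -0.0285 for ribosomal proteins (adjusted p = 0.189 and 0.193) and -0.0505 and -0.0519 for complex I (0.0884 and 0.0817). Both settings also ended the call for serotonin genes (0.0633 and 0.0665), and the first that for nerve markers (0.0521).

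Both needled groups were also compared with the saline controls. After acupoint needling Sprr1a rose by 1.29 (SE 0.18, adjusted p = 0.00502), Hmgn5 by 1.21, Glra3 by 1.17 and Car5b by 1.10, while Tnnt3, Myh4, Atp2a1 and Ckm fell (-2.69, -2.65, -2.55 and -2.52). After hip needling Alas2 rose by 2.6 (SE 0.38, adjusted p = 0.00405), Ppbp by 1.93, Hmgn5 by 1.84 and Sgk3 by 1.67, while Atp2a1, Tnnt3, Myh4 and Ckm fell (-3.55, -3.41, -3.22 and -3.19). Over the 3 MPTP groups together Alas2 rose by 1.93, Hmgn5 by 1.6, Ppbp by 1.36 and Car5b by 1.24, and Atp2a1, Tnnt3, Myh4 and Ckm fell (-3.20, -3.14, -3.06 and -2.97). Single arrays moved several of these values. In acupoint minus control, Hmgn5 was at 0.67 (adjusted p = 0.171), Myh4 at -1.21 (0.0648), Atp2a1 at -1.37 (0.114) and Ckm at -1.68 (0.107) without acupoint replicate 2, and Myh4 was at -4.08 without acupoint replicate 1. Without control replicate 2, Ckm was at -1.61 (adjusted p = 0.164), and Hmgn5, Tnnt3, Myh4 and Atp2a1 did not pass (0.27, 0.0685, 0.211 and 0.24). Hmgn5, Myh4 and Atp2a1 did not pass without any 1 of the MPTP or non-acupoint arrays either (0.0613 to 0.0763), nor Ckm without either MPTP array (0.0518 and 0.051) or Myh4 without control replicate 1 (0.105). In hip minus control, Ppbp was at 0.95 without non-acupoint replicate 1 (adjusted p = 0.073) and at 2.92 without replicate 2, and did not pass without either control array (0.12 and 0.0779). Hmgn5, Atp2a1, Myh4 and Ckm did not pass without control replicate 2 (0.0582, 0.0686, 0.0959 and 0.0526) or without non-acupoint replicate 1 (0.0698, 0.0797, 0.13 and 0.0748), nor Myh4 without control replicate 1 (0.0506). Over the 3 groups, Hmgn5, Atp2a1 and Myh4 did not pass without control replicate 2 (0.0559, 0.0593 and 0.0727), nor Ppbp without either control array (0.224 and 0.107) or either MPTP array (0.0664 and 0.0643). Astrocyte markers were at a mean of 0.42, 0.43 and 0.41 in these comparisons, with 10, 11 and 11 of 15 higher over all genes and 11 in each adjusted over the list alone (adjusted p = 0.808 with an estimated correlation in each). GABA and glycine genes were at 0.39, 0.34 and 0.37, with 10, 10 and 12 of 17 higher over all genes and 11, 11 and 12 adjusted over the list alone (adjusted p = 0.808 with an estimated correlation in each). The GABA-B receptor subunit Gabbr2 was lower over the list alone in hip minus control (-0.29) and over the 3 groups (-0.21). After cyclic loess the means of hip minus control and of the 3 groups were 0.26 and 0.27 for astrocyte markers and 0.19 and 0.24 for GABA and glycine genes. The GABA and glycine call was lost in hip minus control after cyclic loess (adjusted p = 0.0813) and after a further quantile normalization (0.0615). Muscle markers were at -1.91, -2.46 and -2.25, the first at -1.18 without control replicate 2 and -1.23 without acupoint replicate 2.

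These comparisons called 1878 genes after acupoint needling (1530 higher, 348 lower), 3083 after hip needling (2463 and 620) and 4041 for the 3 MPTP groups (3184 and 857). After cyclic loess the splits were 923 and 529, 1576 and 941, and 2206 and 1331, and with arrays centred on their medians 2706 and 166, 4255 and 248, and 5417 and 351. The acupoint count was 249 without control replicate 2, 838 and 846 without MPTP replicates 1 and 2, 3731 without acupoint replicate 1, and 1142 when 1 non-acupoint array, whichever it was, was left out. The hip count was 994 without control replicate 2, 1950 when 1 MPTP array, whichever it was, was left out, 4637 and 4631 without acupoint replicates 1 and 2, and 387 and 1101 without non-acupoint replicates 1 and 2. The count for the 3 groups was 1404 without control replicate 2 and 2591 without MPTP replicate 1.

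Whether needling moved genes back towards control was tested with the covariance, across genes, of the MPTP effect with each needling effect. Both differences contain the MPTP arrays, so a negative covariance arises with no effect, and 2520 assignments of the arrays to groups gave a mean of -0.0207. The spread of the MPTP arrays alone, a value added after seeing the data, gives -0.00669 with no change, and simulated data without effects, in which genes vary independently, gave a mean of -0.0148 for acupoint (range -0.0177 to -0.0132) and -0.0149 for hip needling (-0.0173 to -0.0125). For acupoint needling the covariance was -0.018 (r = -0.448, exact permutation p = 0.838). That is below the values from the MPTP arrays and from simulation, but above the mean of -0.0207 over assignments. For hip needling it was -0.000916 (r = -0.0224, exact permutation p = 0.159), above all of these values, by 0.014 for the simulated mean. Neither differed from other assignments of the arrays by the exact test, and the simulated ranges leave out correlation between genes. The MPTP effect and the difference between the needling sites, which share no array, had a covariance of -0.017 (r = -0.329, exact permutation p = 0.257), against a permutation mean of 0 and -0.00161 to 0.00242 in simulated data. Without acupoint replicate 1 the covariance of the MPTP effect with the acupoint effect was 0.0043 (exact permutation p = 0.205, simulated -0.0148 to -0.0092) and that with the site difference was 0.00522 (exact permutation p = 0.717, simulated -0.00216 to 0.00331). Without non-acupoint replicate 2 that with the hip effect was 0.00698 (exact permutation p = 0.181, simulated -0.0194 to -0.0127). The 2 needling effects had a covariance of 0.00314 (r = 0.181, exact permutation p = 0.212). That is below the 0.0207 that shared MPTP arrays gave on average over assignments, the 0.0149 of simulated data (0.0125 to 0.0179) and the 0.00669 from the MPTP arrays alone, and it was -0.00121 without acupoint replicate 2 (exact permutation p = 0.235, simulated 0.00893 to 0.0151).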

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

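The test of array-wide scaling, the test of adipose tissue on non-acupoint replicate 1, the split of called genes by direction and the comparisons with MPTP replicate 1 alone were chosen only after results were seen, and the other tests below were written before, although every explanation was prompted by genes already seen.

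The lists that differed between the needling sites in camera (effect of acupoint minus hip needling, mean log2) were antioxidant genes (-0.107), caudal Hox genes (0.51), complement (-0.163), ribosomal proteins (-0.0682), dorsal horn peptides (0.13), glucocorticoid-responsive genes (-0.206), immediate early genes (0.116), Schwann cell and peripheral nerve markers (0.678), microglial markers (-0.112), muscle markers (0.557), complex I (-0.0922), neurotrophic factors (0.118) and serotonin genes (0.108). None kept its call with an estimated correlation. Among 6264 probe sets that carry no gene name here and entered no comparison of genes, 315 were higher and 845 lower after MPTP than in controls. Groups of 2 arrays were too small for Dixon's test of a single array far from its group, which was not run.

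When the control arrays were set against the other 6, 4589 genes were called, against 81 at most in the other 27 of the 28 splits of 2 against 6, so chance is excluded only at the limit of this test (1 of 28 splits, the smallest share possible), and the share of variance between the 4 groups gave an exact permutation p of 0.114. Scaling alone does not account for it, because after cyclic loess 2090 genes were called for MPTP minus control, 1764 of them shared. More nuclear or unspliced RNA in the controls may contribute: nuclear-retained or intron-detaining RNAs had a median of -0.399 (23 of 27 measured genes negative, 14 called lower and 0 higher, random lists 0.155), Malat1 among them, which the results also name, and on acupoint replicate 1 minus replicate 2 they had a median of -0.189, where random lists had -0.106. Whether muscle RNA set the controls apart was not decided over all called genes. Called genes off the muscle marker list were displaced towards control on acupoint replicate 1 at 0.523 of the rate of the muscle markers. The 95% interval was 0.443 to 0.631, from a bootstrap over genes rather than samples. Muscle genes off that list, Neb and Pgam2 among them, stayed in this set. The ratio was below the one predicted with muscle RNA as the cause, and its interval reached above the bound predicted without it. It was 0.257 (0.177 to 0.35) for the 486 genes lower after MPTP, below that bound, and 0.628 (0.54 to 0.75) for the 2199 higher ones. All of this is carried by 1 array. Control replicates 1 and 2 had muscle markers at 7.48 and 8.94. Pan-neuronal genes were at 9.995 and 9.992 there, and GABA and glycine genes at 9.34 and 9.30. Acupoint replicate 1, with muscle at 6.99, had these at 10.21 and 9.67, inside the range of the other treated arrays. For these lists, picked after results were seen, no shift followed muscle RNA, and astrocyte and microglial markers (10.56 and 6.89) lay inside that range too. Heat shock genes (9.94, others 10.01 to 10.03) and antioxidant genes (8.99, others 9.09 to 9.17) lay on the control side of it. So did oligodendrocyte markers (10.16, others 10.18 to 10.32) and glucocorticoid-responsive genes (7.70, others 7.76 to 8.10). Lists went both ways on this 1 array, so a shift that follows muscle RNA stays open. Astrocyte (10.216 and 10.095) and microglial markers (6.71 and 6.53) did differ between the controls. The effect of MPTP and any batch shared by the control arrays stay open and untested.

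Acupoint replicate 1 stood apart from replicate 2. Tissue from around the cord in that sample may account for this, since a second list of peripheral nerve and meninges genes was higher on it by a median of 0.686, in 26 of 26 measured genes and above all 10000 random lists, although 1 of these genes, Ngfr, is also on a fixed list. Markers of the same tissues had already been seen to be higher there, so a second list was likely to follow them. Random lists also leave out correlation between genes, so their percentiles overstate the evidence. A rise from needling shared by both acupoint arrays would also show on acupoint replicate 2. There the same genes were at a median of -0.183 relative to the MPTP arrays (3 of 26 positive). Relative to MPTP replicate 1 alone the median was -0.0808 (8 of 26 positive). This argues against a shared rise, but it rests on 1 array and cannot exclude a response in acupoint replicate 1 alone. MPTP replicate 2 was itself higher than MPTP replicate 1, by a median of 0.264 (percentile 100 of random lists), and uneven dissection remains a hypothesis.

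The hormone and lipid genes Fkbp5, Plin4 and Cidea, grouped after their values were seen, were at -0.71, -0.62 and -1.16 in acupoint minus hip needling and did not pass (adjusted p = 0.936 each). Adipose tissue may have contributed, since 11 of 15 adipose markers measured had a median of -0.555 in acupoint minus hip needling (10 negative), but non-acupoint replicate 2 alone carried this, with a median of 1.5 above the acupoint arrays and Fabp4 at 9.05 against 4.25 to 4.99 elsewhere. On non-acupoint replicate 1 the markers were at a median of -0.349, which argues against adipose tissue there. Glucocorticoid exposure cannot be told apart from no exposure: a second list of 22 responsive genes had a median of -0.0314, with 14 negative and 8 positive (percentile 31.7 of random lists). The fixed glucocorticoid list was at a median of 0.00177 on non-acupoint replicate 1 and 0.226 on replicate 2, relative to the acupoint arrays, and a response to hip needling stays open.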

How the results depend on the processing

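The covariates, leaving out acupoint replicate 1 and non-acupoint replicate 1 together ("both arrays out" here), and leave-one-out for the variance share were not planned. The 108 named gene results kept their direction in each of 21 settings that gave them a value, which the 50th percentile filter did for 92, the fits to 2 groups for 100 and averaged probe sets for 106, and 3 of the 48 that passed did so in each. The rule named only genes without overlap between the arrays compared. Leaving out arrays, array weights or other eBayes settings could therefore not turn their direction, and only other scalings or probe sets could. Of 73 lists called, 58 kept the sign of their mean: 11 turned in at least 1 of 16 settings, each with arrays left out, and 4 more with centred arrays. None (0) kept the call in every setting. The 4 were ribosomal proteins in MPTP and in non-acupoint minus control (0.0094 and 0.0022), ATP synthase and complexes II to IV in acupoint minus control (0.051) and rostral Hox genes over the 3 groups (0.041), which stayed at -0.21, -0.22, -0.14 and -0.17 relative to the median gene. The cause was not tested, except that the muscle covariate follows the groups: over the 2696 genes the median size went from 0.492 to 0.286, the median SE from 0.106 to 0.168, and 2600 kept their direction. Leaving out an array leaves a lone array assumed to vary like the other groups. RMA values give no signal over background, so the limit for dim genes is unknown. The replicate numbers did not pair the samples (6 pairs, r -0.328 to 0.174, 2 above 0.1), and a replicate block gave 2210 genes for MPTP minus control, 2181 of them shared. The nerve and meninges covariate gave 3139 (2692 shared).

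For MPTP minus control (2696) the count was 4246 with centred arrays, 289 without moderation, 4159 with array weights and 4 with the muscle covariate, and 69 to 4225 with 1 array left out. Acupoint minus MPTP (0) ranged from 0 to 3. Non-acupoint minus MPTP (0) was 1 with array weights, 2 with only these groups, 14 with both arrays out, and 0 to 13. Acupoint minus non-acupoint (0) was 11 with both arrays out, and 0 to 622. Acupoint minus control (1878) was 2872 centred, 1023 without a trend, 162 without moderation, 667 with weights, 2874 over every probe set (1583 higher, 1291 lower), 3199 with both arrays out, 135 with only these groups, 12 with the muscle covariate, and 249 to 3731. Non-acupoint minus control (3083) was 240 without moderation, 4 with the muscle covariate, and 387 to 4637. The 3 MPTP groups minus control (4041) gave 1357 without moderation, 6112 over every probe set, 9 with the muscle covariate, and 1404 to 5870. The F-test (1724) gave 2778 centred, 531 without a trend, 26 without moderation, 2660 with weights, and 20 to 4030.

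With an estimated correlation 0 lists were called in each of the 7 contrasts. Fry called 9 lists for MPTP minus control, 8 for each needled group minus control and 9 for the 3 MPTP groups minus control. It called 0 for each needled group minus MPTP and 1 for acupoint minus non-acupoint. In camera, a further quantile normalization left 6 for non-acupoint minus control. With 1 array left out, acupoint minus MPTP had 5 to 13 lists and non-acupoint minus control 9 to 16. With both arrays out, list means turned in acupoint minus MPTP for antigen presentation (-0.124, range with 1 array out -0.124 to 0.494), muscle (-0.201, -0.201 to 1.16), complex I (0.00796, -0.231 to 0.00796), neurotrophic factors (-0.0518, -0.0518 to 0.198) and ATP synthase and complexes II to IV (0.0022, -0.117 to 0.0022). They turned in acupoint minus non-acupoint for Schwann cells (-0.406, -0.247 to 1.60), muscle (-0.314, -0.123 to 1.24), complex I (0.0523, -0.212 to 0.0273), neurotrophic factors (-0.055, -0.0071 to 0.243) and ribosomal proteins (0.0166). Reactive astrocyte genes in non-acupoint minus MPTP turned to -0.0165 without MPTP replicate 1. The covariance of the MPTP effect was 0.0043 with the acupoint effect (range -0.0402 to 0.0043) and 0.0131 with the site difference (-0.0393 to 0.00522) with both arrays out, and 0.000186 with the non-acupoint effect at the 50th percentile filter (-0.0105 to 0.00698). No change gives negative values for those with a needling effect. That of the needling effects, positive with no change, ranged from -0.00121 to 0.0108. The variance share ranged from 59.5% to 73.8%.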

Other observations

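The lists here were not called as a whole for MPTP minus control, and single members passed in limma. Of all 16026 genes, 2199 passed higher and 497 lower, so lists of this size hold some such members by that share alone. Of 17 oligodendrocyte and myelin markers 5 rose (Mag by 0.57, Ermn by 0.49, Tspan2 by 0.46, Mal and Cnp), and adjusted over the list alone 6 rose, with Mobp, and Fa2h (-0.28) fell (list mean 0.14, camera adjusted p = 0.18). Among 11 oligodendrocyte precursor markers Lhfpl3 (0.73), Neu4 (0.63) and the growth factor receptor Pdgfra (0.46) rose and Pcdh15 (-0.51) fell by both adjustments (camera adjusted p = 0.327). Of 28 reactive astrocyte genes 5 rose by both adjustments, namely Hspb1 (0.89), Fkbp5 (0.84), Cd109 (0.79), the protease inhibitor Serpina3n (0.69) and the intermediate filament Gfap (0.38), with a camera adjusted p of 0.851. Of 19 glutamate genes the vesicular transporter Slc17a6 (0.75), the AMPA receptor subunits Gria1 and Gria3 (0.55 and 0.56) and the scaffold Dlg4 (0.28) rose by both adjustments (camera adjusted p = 0.655). Of 11 serotonin genes Htr1a (0.60) and Htr3a (0.54) rose over all genes, and Htr2a (0.36) passed over the list alone (camera adjusted p = 0.377).

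Metabolic lists held members that rose and members that fell after MPTP, as did all 16026 genes tested (2199 higher and 497 lower). Among 21 antioxidant genes 7 rose and 1 fell over all genes, and 9 and 1 adjusted over the list alone. The quinone reductase Nqo1 (0.74), Gsr (0.47), Gstm1 (0.46), Gclm, Gsta4, catalase (Cat, 0.34) and Sod2 rose, Gpx4 (-0.28) fell, and Hmox1 (0.42) and Prdx2 passed over the list alone (camera adjusted p = 0.152). Of 19 cholesterol synthesis genes Ebp (0.53), Cyp51 (0.51), Pmvk (0.50), Hmgcs1 (0.48) and Hsd17b7 rose and Fdft1 (-0.31) fell over all genes, and Fdps, Lss and, lower, Dhcr7 (-0.34) were added over the list alone (camera adjusted p = 0.424). Of 33 complex I genes Ndufs1 (0.56), Ndufa9, Ndufs8, Ndufa10 and Ndufv1 rose and Ndufa3 (-0.51) fell by both adjustments (camera adjusted p = 0.958). Of 35 genes of ATP synthase and complexes II to IV, Uqcrfs1 (0.47), Sdhd (0.37), Uqcrc1, Atp5a1 and Sdha rose and Uqcrq (-0.59), Uqcr11 (-0.55), Atp5l (-0.55), Cox6b1 and Atp5j2 fell over all genes, and Uqcrc2 was added over the list alone (camera adjusted p = 0.273). Muscle markers were at a mean of -2.39 in the same comparison. These members were not recomputed with other scalings or with an array left out, and over all genes the count of 2696 was 681 without control replicate 2, 69 without MPTP replicate 1 and 194 without MPTP replicate 2.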
